A study of Homo sapiens with 4 samples.

How the data were processed

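RNA-seq had been done on total RNA from 786-O cells, an established line of human clear cell renal cell carcinoma, stably transduced with a control vector (2 libraries) or with PRDM16 lentivirus (2 libraries). RNA was extracted with a Direct-zol kit and libraries were made with Illumina protocols, per the labels' protocols. Trim Galore, TopHat2 2.1.0, Cufflinks 2.2.1, Cuffdiff and the hg38 build are named in the submitters' processing notes. The gene annotation, the filters, the library scaling and whether the libraries kept strand are not given in the sources used here.

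The deposited table holds 1 value per locus and library. The authors' values were taken as FPKM (fragments per kilobase of transcript, scaled to library size), a unit that the deposited table's header does not name. This reading rests on the tools named and on the values, which are not whole and sum to between 556213 and 574003 per library, so they are neither counts nor TPM. FPKM are already scaled for length and library size, and the exact read numbers behind them are unknown. The table holds 56753 loci, of which 54388 carry 1 gene name and 2365 carry several. Of the single names, 60.3% were found in GENCODE release 29 on GRCh38, the assembly that hg38 refers to. Gene coordinates are from that annotation, which may differ from the one the authors used. Because a locus with several names gives 1 summed value, gene lists were matched only to loci naming that single gene. Loci naming mitochondrially encoded genes were listed at 0 in all 4 libraries, so a 0 elsewhere may also be a failed estimate.

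Depth was compared through the lowest values, where the value of a single read sets the step. Among loci under 0.3 FPKM, the most frequent ratio put control vector replicate 2 at 1.39 times, PRDM16 replicate 1 at 1.25 times and PRDM16 replicate 2 at 1.17 times the depth of control vector replicate 1. The absolute depth is unknown, and no counting interval is given for any FPKM.

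Groups were taken from the vector each sample was labelled with. Loci with a mean FPKM of at least 1 over the 4 libraries were tested in R 4.3.3 with limma 3.58.1. The linear model was fitted to log2(FPKM + 1), with a variance trend and a two-sided moderated test, and p was adjusted by Benjamini-Hochberg with a threshold of 0.05. Changes are given on that scale, which understates the change of low genes. With 2 libraries against 2 there are only 3 splits, so a two-sided exact permutation test cannot go below p = 0.333, and only model p-values are given. Gene lists (29, of which 23 had at least 5 tested members) were tested with camera at a preset correlation between genes of 0.01, adjusted over the 23 lists. The estimated correlation and fry were run as alternatives. With an estimated correlation, camera rests on the 2 residual degrees of freedom, so few lists could pass whatever their correlation. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.

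The gene lists, tests, thresholds and the rule for naming genes were set before the data were examined. That rule named PRDM16 and 14 preset genes of the hypoxia response, the semaphorins and fat biology whatever their values, of which 1 is not reported here. It also took up to 12 of the largest rises and 12 of the largest falls past the threshold. Those had to have non-overlapping libraries and a mean FPKM of at least 5 in the higher group, and symbols of several non-coding classes and loci with several names were left out. From each list it took up to 4 members past the threshold, or the 2 with the smallest p, given as values. The 20 protein-coding loci with the smallest p after PRDM16 were added after their values were seen, with the same FPKM minimum.

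Alternatives covered pseudocounts of 0.1 and 0.5, no filter or a mean FPKM of at least 5, equal medians, quantile normalization, median-of-ratios scaling, no variance trend, robust variances, the replicate number as a block, leaving out each library, a 2-fold minimum and an adjusted p under 0.01. A test of protein-coding loci alone and a list test including loci with several names were added after seeing the data. The count-based tools planned in case the file held counts were not run. The test was checked on simulated data with the 13246 tested loci, in 10 draws. In each draw, 200 protein-coding loci with a mean FPKM of at least 5 were changed. Noise was independent between loci and used each locus's own SD within groups. The test recovered 0.8% of genes changed by 0.5 on the log2 scale and 42.4% of those changed by 1. It recovered 82% of those changed by 2 and 92.4% of those changed by 3, with a mean of 3.1 false calls. These rates do not cover changes at lower or non-coding loci. In 50 draws with independent genes, a shift of the HIF target list by 0.3 was called in 100% of draws. Unshifted lists had an unadjusted camera p under 0.05 in 4.12% of cases. In the data, the estimated correlation was 0.13 for HIF target genes, 0.93 for cell cycle genes and 0.98 for ATF4 and unfolded protein response genes. The check with independent genes does not cover such correlation.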

Results

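RNA-seq profiles were compared between 786-O cells carrying PRDM16 and cells carrying a control vector, to find how PRDM16 overexpression affects the transcriptome of these cells. The line comes from a clear cell renal cell carcinoma and lacks functional VHL, the protein that marks HIF alpha subunits for destruction. PRDM16 encodes a zinc finger regulator of transcription best known for its role in brown fat. Each group had 2 libraries, with 23138 and 24490 loci above 0 in the control vector and 23700 and 23507 in PRDM16. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

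PRDM16 itself rose from 0.0157 and 0.234 FPKM in the control vector libraries to 1226 and 1146 FPKM in the PRDM16 libraries. The gene (locus XLOC_000077) lies on chromosome 1 at 3069168 to 3438621 on the plus strand of hg38. Its mean was 0.125 ± 0.155 against 1186 ± 56.0 FPKM (SD, n = 2 each). The log2 change was 10.05 (SE 0.13), with a limma adjusted p of 0.000317. The value sums any endogenous and vector-derived transcript.

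Beyond PRDM16, no gene annotated as protein-coding passed the test. Of 13246 loci tested, 3 were called by limma at an adjusted p under 0.05, namely PRDM16 and a pair of clone-named loci of unknown function. AL132768.1 rose from a listed 0 in both control vector libraries to 239 and 126 FPKM, with an adjusted p of 0.0308. AC012168.1 fell from 132 and 72.7 FPKM to a listed 0 in both PRDM16 libraries, with the same adjusted p. Each of these 2 loci lost its call when either library listing it at 0 was left out (limma adjusted p from 0.0858 to 0.146) and without the filter on low values (0.526). Among all loci, 811 had an unadjusted p under 0.05, of which 321 were higher and 490 lower with PRDM16, where chance gives 662. With 1 library left out, only the spread of the other group is left as error, so the number of such loci follows that spread. The median absolute log2 difference was 0.190 between the control vector libraries and 0.098 between the PRDM16 libraries. Leaving out a library therefore cannot tell whether the excess of lower loci belongs to PRDM16. Both PRDM16 libraries lay above both control vector libraries at 21.1% of loci and below at 20.3%, where chance gives 16.7% each. The spread of change against level is shown in the plot of all tested loci.

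**Figure D1:**
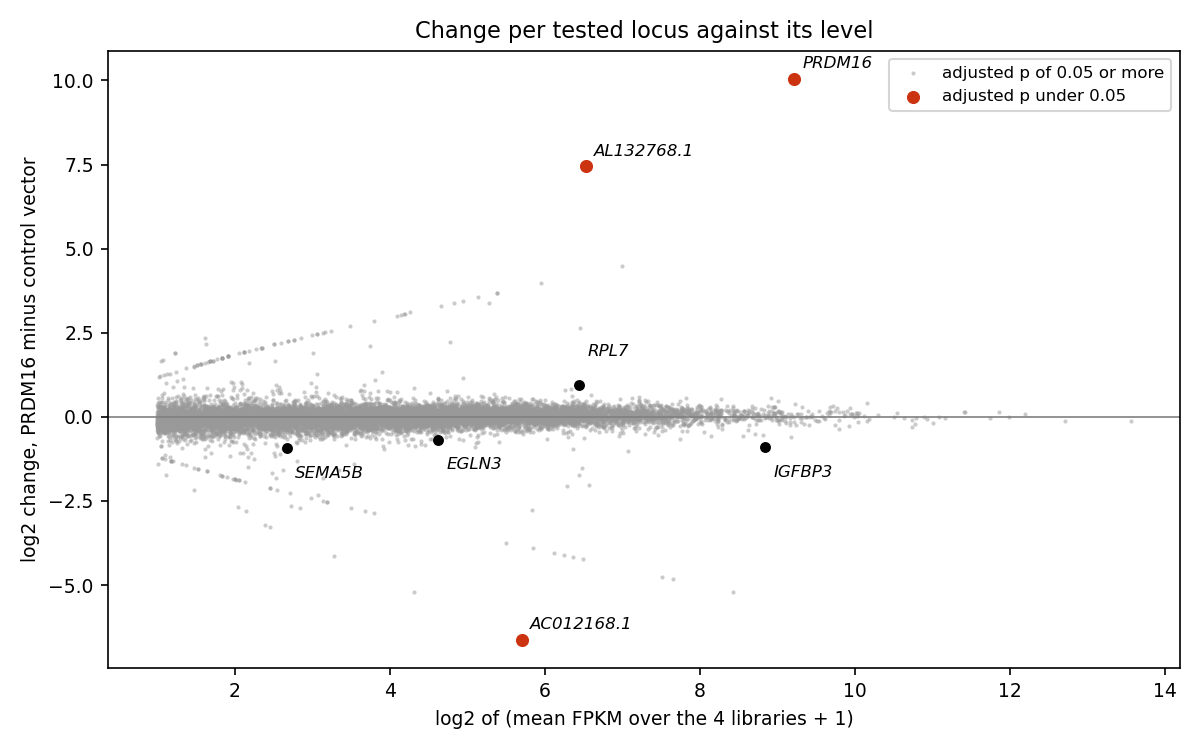
Each point is 1 of 13246 tested loci, with log2 of the mean FPKM plus 1 on the x axis and the log2 change (PRDM16 minus control vector) on the y axis. Red points are the 3 loci past the threshold, PRDM16 at 10.05, AL132768.1 at 7.44 and AC012168.1 at -6.63, and the black points are 4 named genes that did not pass.

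Genes of the HIF pathway, which is active in cells without VHL, were mostly lower with PRDM16. Of 34 tested HIF target genes, 29 had a lower and 5 a higher mean, and 12 lay lower in both PRDM16 libraries than in both control vector libraries. The mean log2 change was -0.18 (camera adjusted p = 0.00189), and the call was lost with an estimated correlation (adjusted p = 0.631). No member passed over all genes, and 1 fell when adjusted over the list alone. That gene was IGFBP3, which encodes a carrier of insulin-like growth factors, at 599 ± 54.8 FPKM in the control vector and 318 ± 10.3 FPKM in PRDM16 (SD, n = 2), 1.88-fold lower. It lies on chromosome 7 at 45912245 to 45921874. NDRG1, a hypoxia-induced gene, was 341 and 759 FPKM against 360.3 and 338 FPKM. VEGFA, the main angiogenic growth factor, was 159 and 279 FPKM against 184 and 173 FPKM. For the glucose transporter SLC2A1 the values were 909 and 1090.0 FPKM against 852 and 702 FPKM. ANGPTL4 went the other way, at 9.69 and 6.24 FPKM against 14.8 and 21.2 FPKM, a log2 change of 1.09 (SE 0.26) that did not pass (limma adjusted p = 0.689). Control vector replicate 2 had the highest list mean, and without it the mean change of the list was -0.06 (camera adjusted p = 0.322), while without control vector replicate 1 it was -0.30.

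The other preset genes of this pathway showed differences that did not pass the test. TGFA, LOX and CCND1 had log2 changes of -0.02, -0.02 and 0.07, each within overlapping libraries (limma adjusted p from 0.798 to 0.978). Without control vector replicate 2, the log2 changes of LOX, VEGFA and NDRG1 were above 0, at 0.32, 0.16 and 0.03. LOX was also higher, at a log2 change of 0.01, after quantile normalization. CA9 was below the filter, at a mean of 0.511 FPKM in the control vector and 0.423 FPKM in PRDM16.

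Oxygen sensing genes and HIF subunits did not pass as a list (6 tested, 5 lower, mean log2 change -0.27, camera adjusted p = 0.0561). They were called lower with a mean FPKM of at least 5 (camera adjusted p = 0.0284), while the mean change was -0.15 without control vector replicate 2 (0.322) and -0.16 with loci of several names included (0.291). EGLN3, a HIF prolyl hydroxylase, fell when adjusted over the list alone, from 29.3 ± 3.64 to 17.8 ± 1.78 FPKM (SD, n = 2), 1.65-fold, and did not pass over all genes (limma adjusted p = 0.689). It is annotated on chromosome 14 at 33924231 to 34462774. EPAS1, the main HIF alpha subunit of these cells, was 79.6 and 141 FPKM in the control vector and 74.0 and 63.6 FPKM in PRDM16, a log2 change of -0.62 (SE 0.29) that was -0.21 without control vector replicate 2 and -1.03 without control vector replicate 1. VHL was 23.6 ± 2.28 against 23.8 ± 0.0675 FPKM, a log2 change of 0.01 that was -0.000532 after quantile normalization. HIF1A was measured only in a locus that also names SNAPC1, at 130.3 ± 5.09 against 144 ± 5.96 FPKM.

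Semaphorins, plexins and neuropilins, the ligands and receptors of a cell guidance system, were lower as a list. Of 23 tested members, 20 had a lower mean and 10 lay lower in both PRDM16 libraries. The mean log2 change was -0.23 (camera adjusted p = 0.000762), and the call was lost with an estimated correlation (adjusted p = 0.631). No member passed, over all genes or adjusted over the list alone. SEMA5B (chromosome 3, 122909082 to 123028605), one of the preset genes, was 5.72 and 9.12 FPKM in the control vector and 3.46 and 3.15 FPKM in PRDM16, 2.25-fold lower on the means. Its log2 change was -0.94 (SE 0.22, limma adjusted p = 0.689). SEMA6D was 2.49 ± 0.0526 against 1.33 ± 0.0381 FPKM, and SEMA7A was higher, at 76.6 ± 0.117 against 106 ± 9.05 FPKM. Without control vector replicate 2 the call was lost (camera adjusted p = 0.0577), at a mean change of -0.18.

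**Figure D2:**
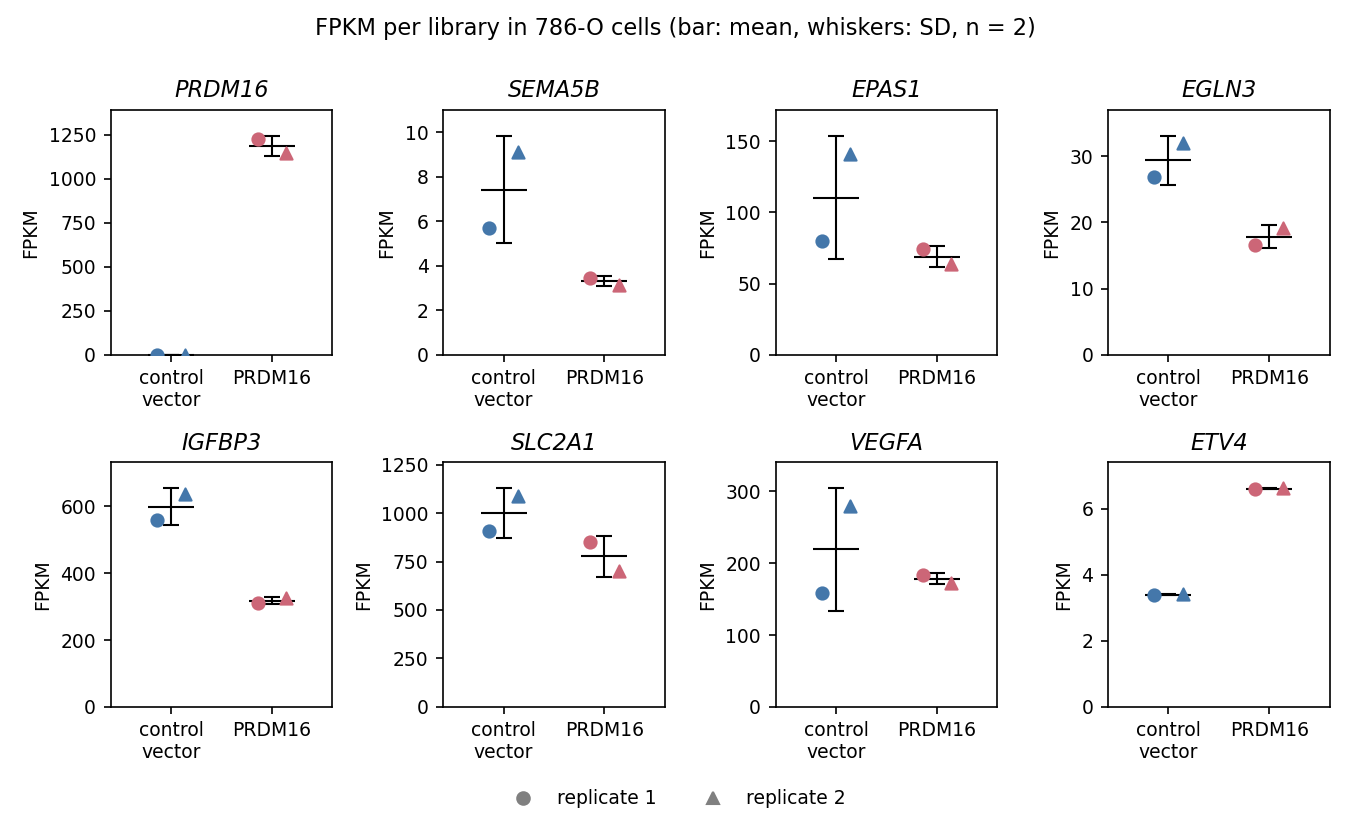
FPKM of 8 genes per library (circle, replicate 1; triangle, replicate 2) in control vector (blue) and PRDM16 (red) libraries, with the mean as a bar and the SD as whiskers (n = 2). PRDM16 separates the groups by the widest margin, at a log2 change of 10.05, while for EPAS1 and VEGFA control vector replicate 2, at 141 and 279 FPKM, lies above the other 3 libraries.

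Mesenchymal and extracellular matrix genes were lower as a list. Of 21 tested, 17 had a lower mean and 12 lay lower in both PRDM16 libraries, with a mean log2 change of -0.15 (camera adjusted p = 0.0038, and adjusted p = 0.631 with an estimated correlation). The matrix glycoprotein gene TNC was 61.0 and 61.5 FPKM against 49.0 and 46.0 FPKM, and the smooth muscle actin gene ACTA2 was 9.84 ± 0.109 against 7.65 ± 0.0625 FPKM. No member passed over all genes or adjusted over the list alone. Without PRDM16 replicate 2 the camera adjusted p was 0.0727. Epithelial junction genes (8 tested, 6 lower, mean log2 change -0.13) did not pass, with a camera adjusted p of 0.125, and their mean change was -0.01 without control vector replicate 2 (camera adjusted p = 0.630) and -0.05 with loci of several names included (0.505). EPCAM among them was 11.4 ± 1.97 against 8.02 ± 1.05 FPKM, and the kidney cadherin CDH16 was 1.72 ± 0.201 against 0.962 ± 0.0505 FPKM.

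Ribosomal protein genes were higher as a list. Of 19 tested, 18 had a higher mean and 11 lay higher in both PRDM16 libraries, with a mean log2 change of 0.19 (camera adjusted p = 0.000471, and adjusted p = 0.631 with an estimated correlation). RPL7 rose when adjusted over the list alone, from 58.1 ± 1.40 to 114 ± 14.9 FPKM, and did not pass over all genes (limma adjusted p = 0.447). RPS12 was 181 ± 8.20 against 239 ± 17.8 FPKM. These genes have processed pseudogenes that share their reads, so single values are uncertain. Without control vector replicate 1 the camera adjusted p was 0.0883, and with loci of several names included (35 tested) the mean change was 0.12.

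Cell cycle genes were higher as a list, with 30 of 31 tested members higher, a mean log2 change of 0.33 and a camera adjusted p of 0.000146 (adjusted p = 0.641 with an estimated correlation). Only 4 of them lay higher in both PRDM16 libraries than in both control vector libraries. Control vector replicate 2 was far below the other 3 libraries, which lay close together. The replication helicase gene MCM4 was 261 and 113 FPKM in the control vector and 229.6 and 249 FPKM in PRDM16. Without that library the mean change was -0.01 (camera adjusted p = 0.816), and without control vector replicate 1 it was 0.67. Among the mitotic genes CDC20 was 132 ± 18.4 against 159 ± 2.45 FPKM and AURKB was 81.8 ± 17.7 against 103 ± 3.71 FPKM.

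ATF4 targets and unfolded protein response genes, which respond to amino acid shortage and misfolded protein, were lower as a list. All 22 tested members had a lower mean, while only 1, VLDLR, lay lower in both PRDM16 libraries. The mean log2 change was -0.29 (camera adjusted p = 0.0137, and adjusted p = 0.645 with an estimated correlation). The chaperone gene HSPA5 was 270.2 and 650.4 FPKM in the control vector and 376 and 276 FPKM in PRDM16, so control vector replicate 2 was again the library apart. Without it the mean change was 0.14, in the opposite direction (camera adjusted p = 0.0683). It was -0.72 without control vector replicate 1, -0.49 without PRDM16 replicate 1 and -0.09 without PRDM16 replicate 2 (camera adjusted p = 0.366). Without the filter on low values the adjusted p was 0.0832.

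Target genes of p53 were lower as a list (14 of 18 lower, 9 in both PRDM16 libraries, mean log2 change -0.17, camera adjusted p = 0.0149, and adjusted p = 0.641 with an estimated correlation). CDKN1A, which encodes an inhibitor of the cell cycle, was 88.9 ± 12.9 against 63.5 ± 3.27 FPKM, and ZMAT3 was 5.48 ± 0.833 against 3.46 ± 0.481 FPKM. The mean change was -0.05 without control vector replicate 2 (camera adjusted p = 0.322), -0.10 without PRDM16 replicate 2 (0.0923) and -0.29 without control vector replicate 1. With a mean FPKM of at least 5 it was -0.12 (camera adjusted p = 0.121). Immediate early and heat shock genes were higher as a list (10 of 14 higher, 9 in both PRDM16 libraries, mean log2 change 0.14, camera adjusted p = 0.0412, and adjusted p = 0.631 with an estimated correlation). FOSL1, a subunit of the AP-1 transcription factor, was 254 ± 41.2 against 361 ± 15.3 FPKM, and MYC was 67.9 ± 0.616 against 82.9 ± 7.32 FPKM. That call was lost without control vector replicate 1, PRDM16 replicate 1 or PRDM16 replicate 2 (camera adjusted p = 0.0883, 0.104 and 0.0770) and after quantile normalization (0.0620).

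**Figure D3:**
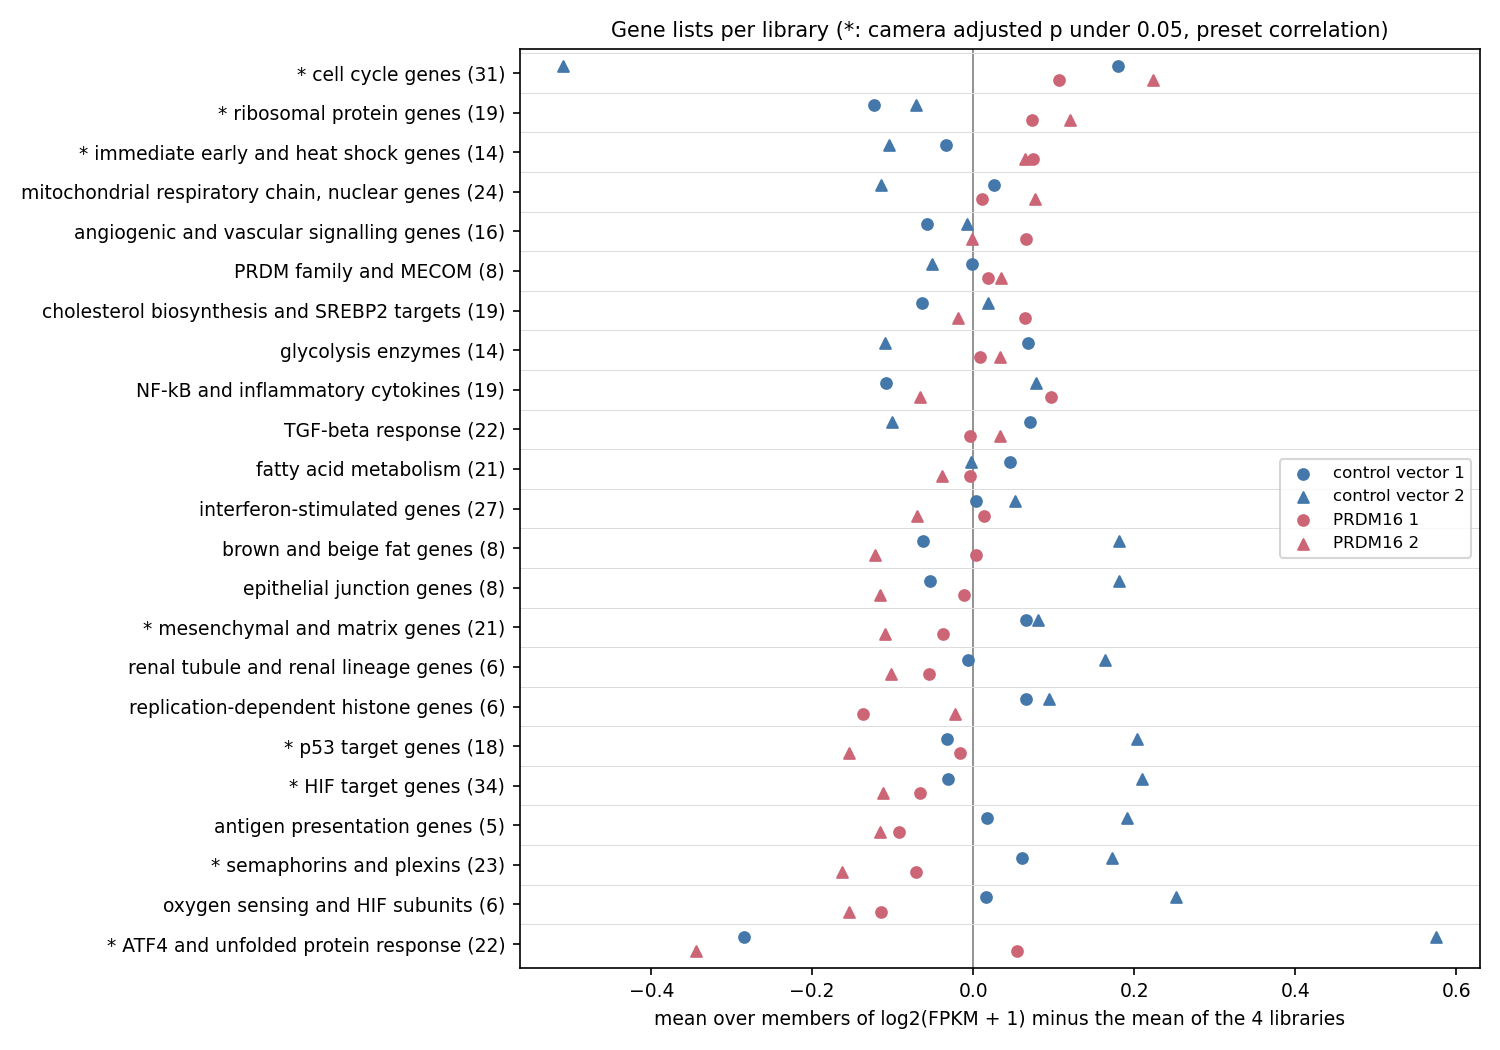
Mean over the members of each of the 23 tested lists of log2(FPKM + 1) minus the mean of the 4 libraries, per library (blue, control vector; red, PRDM16; circle, replicate 1; triangle, replicate 2). Members tested are in brackets and an asterisk marks the 8 lists with a camera adjusted p under 0.05 at the preset correlation. Control vector replicate 2 lies apart for cell cycle and ATF4 genes, while both groups separate for ribosomal protein, semaphorin and matrix genes. The groups also separate for HIF target genes, for immediate early and heat shock genes and for some lists without an asterisk.

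Genes of brown and beige fat, in which PRDM16 is known to act, did not pass as a list (8 tested, 6 lower, mean log2 change -0.12, camera adjusted p = 0.297), and the mean change was 0.00236 without control vector replicate 2 (camera adjusted p = 0.963). PPARGC1A, a coactivator of mitochondrial genes, was below the filter at 0.405 and 0.662 FPKM against 0.547 and 0.156 FPKM. The thermogenic gene UCP1 was listed at 0 in all 4 libraries. Nuclear genes of the respiratory chain were higher in 18 of 24 cases, with a mean log2 change of 0.09 that did not pass (camera adjusted p = 0.0578). The mean change was 0.02 without control vector replicate 2 (camera adjusted p = 0.504) and 0.16 without control vector replicate 1 (0.0376). The list was also called higher without PRDM16 replicate 1 (camera adjusted p = 0.0359), without the filter on low values (0.0278) and with loci of several names included (0.0208). Other settings gave the respiratory chain genes a smaller rise. Their mean change was 0.050 after quantile normalization (camera adjusted p = 0.332) and 0.054 without PRDM16 replicate 2. The mitochondrially encoded genes were not tested. Other PRDM genes (8 tested, 5 higher) had a mean log2 change of 0.05 (camera adjusted p = 0.469).

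The remaining lists did not pass. Across the 23 tested lists no member passed over all genes, and the members that passed adjusted over the list alone were IGFBP3, EGLN3, RPL7 and IL11. Antigen presentation genes (5 tested, 5 lower) had a mean log2 change of -0.21 (camera adjusted p = 0.0561), renal lineage genes (6 tested, 6 lower) -0.16 (0.0867) and replication-dependent histone genes (6 tested, 5 lower) -0.16 (0.233). Antigen presentation genes were called lower without the filter on low values (camera adjusted p = 0.0479) and with loci of several names included (0.0208). Without control vector replicate 2 their mean change was -0.12 (camera adjusted p = 0.322), and that of renal lineage genes was -0.07 (0.504), as it was with loci of several names included (0.410). Camera adjusted p was 0.248 for cholesterol synthesis genes, 0.471 for glycolysis enzymes, 0.484 for fatty acid metabolism and 0.507 for interferon-stimulated genes. It was 0.363 for NF-kB and cytokine genes, where the test and mean pointed up and the median down (-0.02). It was 0.696 for angiogenic genes, again with a median below 0 (-0.05), and 0.762 for TGF-beta response genes, where the test pointed down and the mean up (0.03). Glycolysis and TGF-beta response genes had mean changes below 0, at -0.05 and -0.06, without control vector replicate 2. IL11, a cytokine gene in the NF-kB list, rose when adjusted over the list alone, from 16.5 ± 1.72 to 27.4 ± 0.149 FPKM, and did not pass over all genes (limma adjusted p = 0.616). The NF-kB list was called higher once control vector replicate 2 was left out, at a mean log2 change of 0.12 (camera adjusted p = 0.0419), and its mean was -0.06 without control vector replicate 1.

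Markers of other cell types were near the floor, with medians per library of at most 0.133 FPKM in the leukocyte, endothelial, neuronal, fibroblast and muscle lists. Members at a mean of 1 FPKM or more were few. LCP1, an actin-bundling protein gene that many carcinoma lines also express, rose when adjusted over its list alone (2 tested), from 13.2 ± 1.35 to 24.6 ± 1.54 FPKM (limma adjusted p over all genes = 0.478). CSF1R was 2.71 ± 0.849 against 2.94 ± 0.144 FPKM, TIE1 1.85 ± 0.416 against 2.50 ± 0.217 FPKM and EGFL7 11.6 ± 1.54 against 11.9 ± 1.63 FPKM. NEFL was 91.4 ± 24.4 against 66.4 ± 2.56 FPKM, LUM 2.11 ± 0.144 against 2.23 ± 0.136 FPKM, COL1A1 1.69 ± 0.615 against 1.87 ± 0.389 FPKM and TNNT1 51.7 ± 8.65 against 42.3 ± 2.36 FPKM.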

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

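PRDM16 was called in every setting, with a log2 change from 9.85 (quantile normalization) to 12.56 (pseudocount 0.1). The number of called loci was 3. It was 5 with a pseudocount of 0.1, 1 without a filter on low values, 6 without a variance trend, 5 with robust variances, 1 at an adjusted p under 0.01 and, in a test chosen after seeing the data, 1 among 10313 protein-coding loci (764 at an unadjusted p under 0.05, where chance gives 516). Leaving out 1 library gave 16 to 39 loci, of which 2 were shared with the 3 in each case. They were 39 without control vector replicate 1, 30 without control vector replicate 2, 18 without PRDM16 replicate 1 and 16 without PRDM16 replicate 2, with the lone library assumed to vary like the other group. Apart from PRDM16, the loci called with a library left out were mostly short non-coding RNA or clone-named loci. Most were lower when a control vector library was left out, and all were higher when a PRDM16 library was left out. Either way the lone library mostly held the higher value, so these directions follow the library left out and say nothing about PRDM16. The cause of these changes in number was not tested. The count-based alternative was not run, since the table holds FPKM.

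The number of called lists was 8. It was 0 with an estimated correlation, 0 with fry, 10 when loci with several names were included (chosen after seeing the data) and 4 to 8 with 1 library left out, the lowest without control vector replicate 2 or PRDM16 replicate 2. A call lost with an estimated correlation does not measure correlation alone, since that run rests on 2 residual degrees of freedom. For immediate early and heat shock genes the estimated correlation was -0.0683, under the preset 0.01. Their unadjusted camera p still went from 0.0143 to 0.121. Cell cycle genes ranged from -0.0147 to 0.674 and ATF4 and unfolded protein response genes from -0.720 to 0.140 with 1 library left out. The replicate block gave 5 loci and 9 lists, adding oxygen sensing genes (camera adjusted p = 0.0439), and 422 loci at an unadjusted p under 0.05 against 811. Same-numbered libraries did not deviate together (correlation -0.0584, across loci), and the numbers are not known to mark pairs.

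Among 79 other named genes and 1168 comparisons with the alternatives, 16 reversed, in 10 genes, none of which had passed the test. With quantile normalization VHL was -0.000532 and LOX 0.00504. With 1 library left out, the lowest and highest log2 changes were -0.0104 and 0.157 for CCND1, -0.128 and 0.343 for COL1A1, -0.131 and 0.340 for CSF1R, -0.0942 and 0.165 for EGFL7, -0.661 and 0.00671 for HIST1H4H, -0.362 and 0.320 for LOX, -1.12 and 0.0341 for NDRG1, -0.0398 and 0.00583 for TGFA, -0.647 and 0.162 for VEGFA and -0.0830 and 0.106 for VHL. The cause was not tested.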

Other observations

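Leaving out each library was a planned setting. The depth test, and weighing the HIF target and semaphorin lists by the values without control vector replicate 2, were chosen only after the result was seen, and the genes of the next paragraph were named after their values were seen.

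Several of the 20 protein-coding genes with the smallest p after PRDM16 had tight replicates, which a ranking by p with n = 2 favours. None of the 20 passed the threshold (limma adjusted p from 0.175 to 0.689). Of these, IGFBP3, RPL7, IL11 and LCP1 belong to fixed lists, and the genes below do not. AIF1L, an actin-binding protein gene, was 5.74 ± 0.698 FPKM in the control vector and 1.81 ± 0.00303 FPKM in PRDM16 (SD, n = 2). RARRES2, which encodes the chemoattractant chemerin, was 260.2 ± 10.5 against 165 ± 2.54 FPKM. ALDH1A1, which makes retinoic acid, was 43.8 ± 6.42 against 22.8 ± 1.23 FPKM. The secreted matrix proteins MATN2 and CRISPLD2 were 22.5 and 27.5 FPKM against 13.6 and 12.7 FPKM, and 25.9 ± 0.762 against 14.4 ± 1.96 FPKM, in that order. In the other direction, PDPN, a membrane glycoprotein gene, was 18.9 ± 2.07 against 32.6 ± 0.109 FPKM, and G0S2, an inhibitor of fat breakdown, was 111 ± 3.33 against 165 ± 7.60 FPKM. RPS28 was 1.78 ± 0.410 against 7.68 ± 0.238 FPKM, and its reads can be shared with near-identical copies.

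Control vector replicate 2 stood apart from the other 3 libraries. Over its own deviations from the mean of those libraries, 13 replication genes had a median of -1.02, 15 mitotic genes -0.40 and 22 ATF4 and unfolded protein response genes 0.81 on the log2 scale. An effect of sequencing depth on low genes alone is argued against, since 22 cell cycle genes with a mean of at least 50 FPKM still had a median of -0.511 there. The other libraries had 0.126 to 0.259, but their deviations are taken from means that include control vector replicate 2. The 22 genes also belong to the list that marked this library as apart, so lying outside that range adds little. Gene length and GC content are argued against too, since removing their trend left the cell cycle median at -0.626 (before, -0.680). The 95% sign-test interval, -0.897 to -0.437, was taken over 31 genes as if independent and measures no spread between libraries. A difference in cell density, medium or culture stage remains open and was not tested, because the labels give none.

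Lower HIF target genes may rest largely on that library. Without it the mean log2 change was -0.0574 for HIF targets (camera adjusted p = 0.322) and -0.177 for semaphorins and plexins (camera adjusted p = 0.0577). For HIF targets control vector replicate 1 (a mean deviation of -0.03 from the mean of all libraries) lay above both PRDM16 libraries (-0.07 and -0.11), by a small margin. For them an effect of PRDM16 and a high control library cannot be told apart. Semaphorins lost their call too but most of their change of -0.233 stayed, with control vector replicate 1 (a mean deviation of 0.06) above both PRDM16 libraries (-0.07 and -0.16). Camera also called HIF targets, and not semaphorins, in the split that set control vector replicate 2 and PRDM16 replicate 1 against the others. IGFBP3 and EGLN3, the HIF targets with the smallest p, were lower in both PRDM16 libraries than in both control vector libraries. So were 20.3% of all tested loci, and this adds little.

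The called loci AL132768.1 and AC012168.1 might reflect a few reads on very short transcripts, where a single read gives a high FPKM. As a test, 0 of the 2 loci had a value held by another locus, as single reads on equal lengths would give. That test turned out too weak to exclude the explanation, since among microRNA and small nucleolar RNA loci above 0 only 20.9% to 31.1% shared their value with another locus. Neither name is in GENCODE 29, so no length was available here, and the explanation cannot be told apart from a real change.

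With 4 libraries there are 3 splits into 2 and 2, too few for a share under 0.05. The real split called 3 loci and the highest of the other splits 7. Among protein-coding loci the real split called 1 and the others 0 (limma), with 764, 45 and 441 at an unadjusted p under 0.05 in the real split, the split by replicate number and the crossed split. At the preset correlation, camera called 8 lists in the real split, 2 in the split by replicate number and 6 in the crossed one, which sets control vector replicate 2 and PRDM16 replicate 1 against the others. Cell cycle and ATF4 genes were called in all 3 splits. Control vector replicate 2, with mean deviations of -0.51 and 0.58 for these lists, shifts a group in every split. These calls therefore repeat the deviation of that library and are no separate evidence.

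A hypothesis is that target genes of ERK signalling are higher with PRDM16. It arose from 9 tested genes noticed for their small p, IL11, HBEGF, PHLDA1, EMP1, FOSL1, ETV4 (3.40 ± 0.00557 against 6.60 ± 0.00668 FPKM), DUSP6 (3.23 ± 0.194 against 5.40 ± 0.142 FPKM), SPRY4 (1.17 ± 0.0882 against 2.43 ± 0.0866 FPKM) and HMGA1 (57.9 ± 11.1 against 102 ± 4.02 FPKM). Of 14 other ERK targets, 12 were tested and 9 were higher, with a mean log2 change of 0.195. Camera gave p = 0.00128 at the preset correlation and p = 0.159 with an estimated one, so the question stays open. Without EPHA2 and LIF, which also belong to lists tested earlier, the mean was 0.21 over 10 genes. Camera then gave p = 0.00204 at the preset correlation and p = 0.0964 with an estimated one. That estimate was 0.0183, near the preset 0.01. The higher p thus comes mainly from the 2 residual degrees of freedom used with an estimated correlation. Leaving out control vector replicate 2 gave the 12 genes a mean of 0.15 and a camera p of 0.00196 at the preset correlation. PLAUR (59.5 ± 0.201 against 78.5 ± 1.57 FPKM) and EPHA2 (136 ± 3.93 against 164 ± 9.21 FPKM) were among the higher ones, while EPHA4 was 4.73 ± 0.836 against 3.14 ± 0.408 FPKM.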
